A study of Homo sapiens with 6 samples.

How the data were processed

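RNA of 2 human cell lines was sequenced, with 3 samples per line. HBE is a line of normal lung epithelial cells, whose name the labels also spell HEB, and A549 is a line of lung adenocarcinoma cells. Per the labels' protocols, HBE was grown in RPMI-1640 and A549 in DMEM, so the culture medium differed with the line, and the libraries came from total RNA with an mRNA library kit. The labels do not say that the samples of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Whether the counting used the strand of the reads is not given in the sources used here.

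HISAT2, StringTie and DESeq2 and the genome build GRCh38 are named in the submitters' processing notes, without versions. The deposited table holds 1437 lncRNA transcripts that the authors selected. The largest p-value in the authors' deposited table was 0.00997 and the smallest absolute log2 fold change was 1.25. Whether the deposited p-value was adjusted is not given in the sources used here. Transcripts outside that selection were not analysed here. The deposited table gives an estimated count and an FPKM per transcript and sample, and a log2 fold change of A549 over HBE. Of its transcripts, 688 carried Ensembl identifiers and belonged to 602 genes, and 749 were transcripts assembled by StringTie, judging by their identifiers, with no name or position. All 688 identifiers were in GENCODE release 29, which gave positions on GRCh38, exons and lengths, and 676 transcript names were equal there.

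The authors selected the transcripts on the same 6 samples, so a new test on them is not independent evidence that they differ, and the sum of a column is not the depth of its library. The depth was recovered instead. The deposited estimated counts equalled FPKM times transcript length times library size, rounded up, within 1 count for 99.4% to 99.8% of the nonzero annotated values in each sample. The library sizes solved from this relation were 56222625, 51859235 and 49371791 for HBE and 55991534, 55449504 and 57664810 for A549. 1 count was worth 0.0173 to 0.0203 CPM, the estimated count scaled by the library size. All per-sample columns of counts and FPKM were matched to a sample.

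The whole-number estimated counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The recovered library sizes were the only scaling, and no low-count filter or replicate block was used. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Where a line had no count, the fold is a lower bound against 3 counts over the 3 samples of that line. Where a line had 1 to 3 counts, the ratio is given with an exact 95% interval from the binomial distribution. Bounds and intervals cover counting error only. The bounds without each sample of the higher line were added after the data were seen, and are given for bounds in the text that moved by over 1.5-fold. Counts were simulated for these 1437 transcripts, with 200 of them changed between A549 and HBE. On these the test recovered 4.48% of 2-fold, 25.4% of 4-fold and 69.7% of 8-fold changes, and called 1 of 1237 unchanged transcripts. In the data nearly all transcripts passed, so the adjustment was less strict there. The simulated rates are therefore not those of the fit to the selected transcripts.

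The rule for named transcripts was fixed before the data were examined. It took GLIDR and PPARGC1A if measured, and per direction the 10 largest folds and the 5 most abundant. These had to pass the threshold with a symbol, no overlap between the lines and a mean of at least 50 counts in the higher line. Up to 4 members per gene list with the smallest adjusted p, and 2 transcripts without a symbol per direction, were added. Further list members named below, among them FENDRR-205 and the transcripts of LINC00511, GAS5 and SNHG17, fall outside this rule. XIST and Y-linked genes were left out, which removed 3 transcripts from the tables and plots. The 16 gene lists were fixed at the same time and matched by symbol or RefSeq synonym. They were lncRNAs described in lung cancer and in platinum resistance, HOX cluster transcripts, snoRNA and microRNA hosts, imprinted lncRNAs, p53-linked lncRNAs, the NRF2 pathway, 9p21 genes, the PPARGC1A axis, and markers of airway, alveolar and club, mesenchymal, neural, blood and endothelial cells and of proliferation. The split of a list's calls by direction was set against all other calls with Fisher's exact test, two-sided, for lists with at least 5 calls. The same test was run per chromosome and per naming class, and per GENCODE gene type after the data were seen.

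Near-identical copies were sought with BLAST+ 2.17.0 at 97% identity or more among all GENCODE transcripts. Overlaps with exons of protein-coding genes were sought with bedtools 2.31.1. Of the 688 annotated transcripts, 100 had over 50% of their length covered by such copies in other genes. Exons of a protein-coding gene overlapped 194 of them on the opposite strand and 54 on the same strand, and reads of such pairs may not be told apart. Other scalings, DESeq2 1.42.0, limma-voom (limma 3.58.1), count filters, stricter thresholds, a replicate block and leaving out each sample were tried as alternatives. The alternatives for FPKM alone were not run because counts were deposited.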

Results

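Whole-transcriptome sequencing was used to compare lncRNA expression between the normal lung epithelial line HBE and the lung adenocarcinoma line A549, with 3 samples per line. The table covered 1437 lncRNA transcripts chosen by the authors. Its estimated counts summed to 1396936, 1130104 and 489102 in HBE replicates 1 to 3, and to 305905, 254246 and 608749 in A549 replicates 1 to 3. These sums were 0.991% to 2.48% of the HBE libraries and 0.459% to 1.06% of the A549 libraries. RPPH1-201 alone made up 75.5% to 88.09% of the HBE sums and 50.09% to 56.13% of the A549 sums. Without it, a comparison chosen after seeing the data, the sums were 0.215% to 0.609% of the HBE libraries and 0.229% to 0.463% of the A549 libraries. The ranges of the lines overlapped with and without RPPH1-201.

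GLIDR, the lncRNA in the title of the study, was higher in A549 in both of its transcripts in the table. GLIDR-202 (ENST00000625350, chromosome 9, 39807361 to 39810063, minus strand, 2 exons, GRCh38) had 0, 22 and 14 counts in HBE replicates 1, 2 and 3 and 189, 221 and 175 in A549. Its level was 0.236 ± 0.216 CPM in HBE and 3.47 ± 0.482 CPM in A549 (SD, n = 3 each), a log2 fold change of 3.87 with an SE of 0.81. The adjusted p was 7.88e-05 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Without HBE replicate 2 the log2 fold change was 4.62, without HBE replicate 1 it was 3.28, and with DESeq2 size factors it was 5.35. GLIDR-201 (ENST00000618092, 39807381 to 39810058) had no count in HBE and 7, 9 and 22 counts in A549, at least 11.8-fold higher, or at least 7.5-fold without A549 replicate 3. Near-identical transcripts of other genes covered 100% of both, so the counts of GLIDR are uncertain. One such gene, BX088651.4, lies at 42566679 to 42569353 on the same chromosome and was picked after its values were seen. BX088651.4-201 was also higher in A549, at 2.33 ± 0.676 CPM against 0.275 ± 0.193 CPM in HBE (SD, n = 3 each). PPARGC1A was not analysed here.

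**Figure D1:**
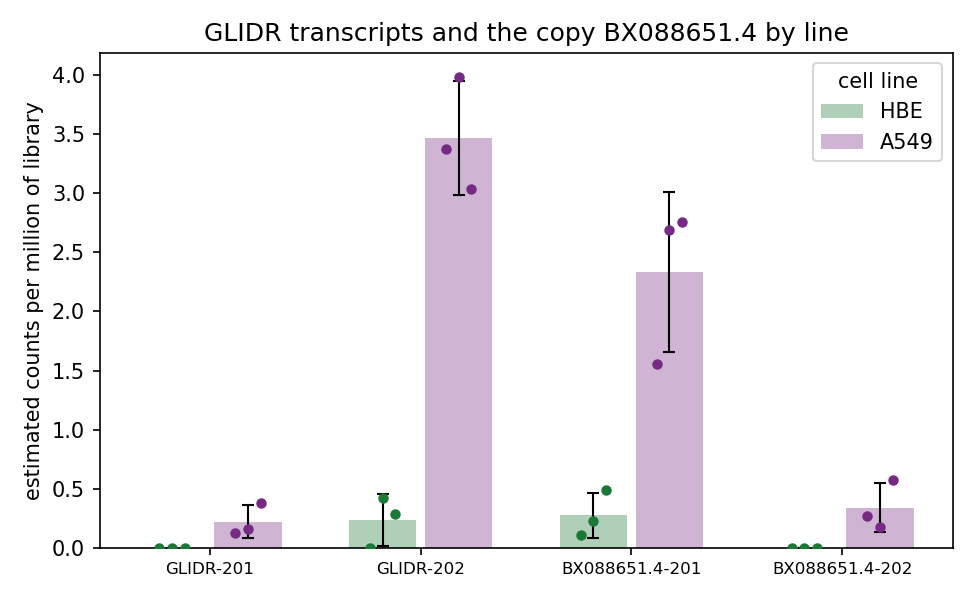
Estimated counts scaled by library size (CPM, y axis) for the transcripts of GLIDR and of its near-identical copy BX088651.4 (x axis) in HBE and A549; bars are means, error bars SDs and points the 3 samples of each line. GLIDR-202 averaged 3.47 CPM in A549 and 0.236 CPM in HBE, and every A549 sample lay above every HBE sample for all 4 transcripts.

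Among transcripts with a symbol and a mean of at least 50 counts in the higher line, the largest folds were those of MIR205HG in HBE and SNHG14 in A549. MIR205HG-205, of the host gene of the epithelial microRNA miR-205, reached 162 ± 75.1 CPM in HBE (SD, n = 3) with no count in A549, at least 8927-fold higher in HBE. AFAP1-AS1-201 stood at 41.9 ± 14.6 CPM in HBE (SD, n = 3) and had 3 counts over all A549 samples, all in replicate 2, a ratio of 2329 with an exact interval of 797 to 11296. Exons of the protein-coding gene AFAP1 lie opposite AFAP1-AS1-201. SNHG14-226, of the imprinted host of the SNORD115 and SNORD116 snoRNAs (chromosome 15, 25041689 to 25120432), had 20.8 ± 9.36 CPM in A549 (SD, n = 3) and no count in HBE. It was at least 1087-fold higher in A549. 1435 of the 1437 transcripts passed the threshold of 0.05, 684 higher in A549 and 751 higher in HBE, so 47.7% were higher in A549. The balance turned with DESeq2 size factors, the DESeq2 Wald test, column totals and TMM over the table, which put 52.41% to 55.24% of calls higher in A549. Upper-quartile factors gave 47.9%, and filters on low counts 40.52% and 41.45%. The authors' own log2 fold changes put 685 transcripts higher and 752 lower in A549, and all 1437 had the same sign as in this fit.

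Among the other transcripts with no count in HBE, AC124312.3-201 was at least 723-fold, AC079062.1-203 at least 415-fold and ZBED5-AS1-201 at least 329-fold higher in A549. LINC02212-201, LINC00662-206, AC092279.1-202, AC129492.1-201, LINC01234-203 and AP000525.1-201 were at least 110-fold to 206-fold higher. Near-identical sequence of DUXAP10 covers 99.7% of AP000525.1-201, so its counts may belong to that gene. Exons of protein-coding genes overlap ZBED5-AS1-201 (ZBED5) and AC129492.1-201 (ALOX12B) on the opposite strand, and AC092279.1-202 (ZNF254) on the same strand. Without A549 replicate 3 the bound of AC124312.3-201 was 404-fold. AC124312.3-201 lies in the SNHG14 region and all of its sequence recurs in SNHG14. With no count in A549, AC004846.1-201 was at least 523-fold and LINC01503-204 at least 274-fold higher in HBE. AC244153.1-201, AC244153.1-203, LNCAROD-202, LINC01819-203, LINC00987-201 and AC073072.1-201 were at least 160.0-fold to 218-fold higher there. The bound of LINC01819-203, 169-fold, was 257-fold without HBE replicate 1. Exons of PAPLN lie opposite AC004846.1-201. AC073072.1-201 overlaps exons of IL6 on the opposite strand and of STEAP1B on the same strand. The assembled transcripts MSTRG.14171.2 and MSTRG.31835.40 had no count in HBE and 338365 and 24925 counts over the A549 samples, and 58.7% of those of MSTRG.14171.2 were in replicate 3. MSTRG.31835.12 and MSTRG.20319.6 had no count in A549 and 237774 and 7084 counts over the HBE samples. HBE replicate 1 held 87.1% of the counts of MSTRG.31835.12 and 57.75% of those of MSTRG.20319.6. Without it the bounds fell from 85123-fold to 17047-fold and from 2536-fold to 1667-fold. Judging by their identifiers, MSTRG.31835.12 and MSTRG.31835.40 belong to 1 assembled locus. The transcripts of that locus in the table summed to 1738 CPM in HBE and 157 CPM in A549. Those of MSTRG.20319 summed to 73.7 CPM in HBE and 10.9 CPM in A549. These bounds therefore hold for single transcripts and not for their loci.

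Of the abundant transcripts present in both lines, AGAP2-AS1-201 rose from 9.30 ± 2.10 CPM in HBE to 30.4 ± 2.93 CPM in A549 (SD, n = 3 each), and 56.4% of it is covered by near-identical transcripts of other genes. SNHG4-202, at 1.44 ± 1.37 CPM in HBE (SD, n = 3), was higher in A549 by a log2 fold change of 4.34 (SE 0.66), or 5.48 without HBE replicate 3. Exons of the protein-coding gene MATR3 overlap SNHG4-202 on the same strand, so reads of the 2 may not be told apart. LRRC75A-AS1-205 and AC007996.1-201 were higher in A549 by log2 fold changes of 2.58 (SE 0.55) and 4.05 (SE 0.58). The former was 1.975 without A549 replicate 3. LRRC75A-AS1 had 5 transcripts in the table, 4 higher and 1 lower in A549, which summed to 17.0 CPM in HBE and 35.8 CPM in A549. Exons of AGAP2 lie opposite AGAP2-AS1-201, and those of LRRC75A opposite LRRC75A-AS1-205. AL356488.2-201 fell from 298 ± 216 CPM in HBE to 10.9 ± 5.32 CPM in A549 (SD, n = 3 each), and 98.4% of it matches the small Cajal body RNA gene SCARNA2. Its log2 fold change was -4.775, or -4.007 without HBE replicate 1. AC245041.2-204 fell from 29.7 ± 5.58 to 3.91 ± 0.784 CPM (SD, n = 3 each) and shares 100% of its sequence with other genes, among them ANXA8. SNHG15-202 fell from 44.8 ± 8.20 to 14.0 ± 5.59 CPM (SD, n = 3 each), a call that was lost with DESeq2 size factors, the DESeq2 Wald test, column totals and TMM over the table. The call of AC245041.2-204 was lost with column totals.

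**Figure D2:**
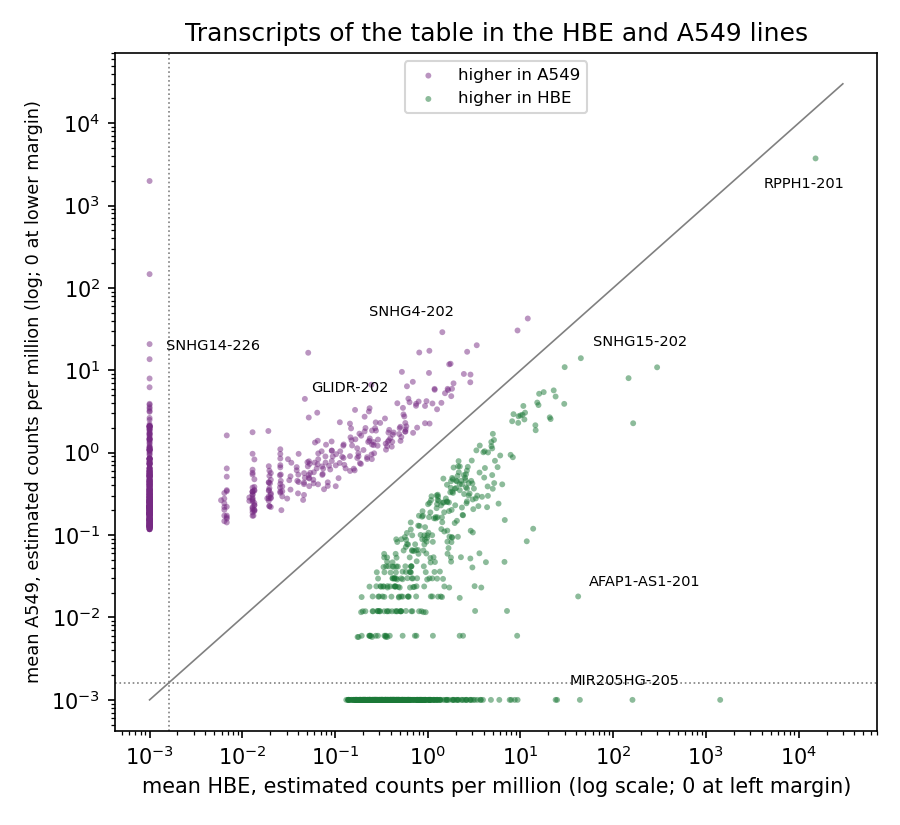
Mean estimated counts scaled by library size (CPM) in HBE (x axis) and A549 (y axis), both on log scales, for 1434 transcripts; points beyond the dotted lines had no count in that line, and the grey diagonal marks equal levels. No count was found in HBE for SNHG14-226 or in A549 for MIR205HG-205, while RPPH1-201 is the most abundant transcript in both lines.

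The lines did not overlap for 1425 transcripts, against 10% by chance for 3 samples against 3, on transcripts that the authors had chosen for their difference. 411 transcripts had no count in HBE and 398 had none in A549. 1088 transcripts, or 75.7%, had a mean below 1 FPKM in both lines. RPPH1-201, the RNA of ribonuclease P, and AC087482.1-204 were the 2 that did not pass. Near-identical sequence of AL355075.4 covers 100% of RPPH1-201. RPPH1-201 measured 15236 ± 6484 CPM in HBE and 3728 ± 1931 CPM in A549 (SD, n = 3 each), with an adjusted p of 0.123 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Both were named after their values were seen.

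The fixed lists asked whether lncRNAs of lung cancer, platinum resistance and cell identity moved together. Because only transcripts selected by the authors on these samples were tested, the counts are not independent evidence of a list's direction, and the same members passed when adjusted over the list alone. Of 34 transcripts of lncRNAs described in lung cancer, 15 were higher and 19 lower in A549. All 7 transcripts of UCA1 in the table were lower in A549, with UCA1-223 at least 148-fold lower, and so were AFAP1-AS1-201 and FENDRR-205. LINC00511 and GAS5 were higher in A549 in all 3 of their transcripts in the table each, and NEAT1-201 rose by a log2 fold change of 5.53 (SE 0.95, n = 3 each), or 4.94 without HBE replicate 1. The 10 HBE counts of NEAT1-201 were all in replicate 2, without which that line had none. Of 21 transcripts in the platinum resistance list, 10 were higher and 11 lower in A549. The split did not differ from that of the other transcripts in either list (Fisher's exact test, two-sided, adjusted p = 0.939 and 1 over 6 lists).

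All 8 HOX cluster transcripts in the table were lower in A549 (adjusted p = 0.0488 by Fisher's exact test, two-sided). HOXA10-AS-202, at 2.04 ± 0.666 CPM in HBE (SD, n = 3), was at least 117-fold lower, HAGLR-202 at least 83.1-fold and HOXA11-AS-205 at least 59.8-fold lower. The bound of HAGLR-202 rested on HBE replicate 3, with 178 of 232 counts, and was 28.2-fold without it. Exons of the protein-coding genes HOXA10 and HOXA9 lie opposite HOXA10-AS, and those of HOXA11 opposite HOXA11-AS. Of 27 transcripts of snoRNA hosts, 19 were higher and 8 lower in A549 (adjusted p = 0.0488 by the same exact test). With DESeq2 size factors and with TMM, both over the table, 3 of the lower calls were left, and with the DESeq2 Wald test and column totals 2, while 19 higher calls were found each time. SNHG14, SNHG4, SNHG17 and GAS5 were higher in A549 in every transcript of the table. All 5 SNHG15 transcripts there were lower in the fit with recovered library sizes. By gene, 5 of the 9 snoRNA hosts in the table were higher, 2 were lower and 2 had transcripts in both directions. The 5 transcripts of imprinted lncRNAs, 4 of SNHG14 and PEG13-201, were all higher in A549 (adjusted p = 0.0488 by the same exact test), and SNHG14 belongs to the snoRNA host list too. With 1 transcript per gene, an alternative chosen after seeing the data, the adjusted p was 0.105 for both the HOX and the snoRNA host lists by the exact test, and the imprinted list was too small to test.

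Of 13 microRNA host transcripts, 7 were higher and 6 lower in A549 (adjusted p = 0.939 by Fisher's exact test, two-sided). The 4 with the smallest adjusted p, MIR205HG-205, MIR205HG-208, MIR205HG-203 and ALOX12-AS1-208, had no count in A549. MIR193BHG-211 and MIR137HG-201, which the naming rule did not pick, were higher there. Exons of ALOX12 lie opposite ALOX12-AS1-208. All 3 airway epithelial transcripts belonged to MIR205HG and were lower in A549, and both alveolar and club transcripts belonged to SFTA1P and were lower too, with SFTA1P-203 at least 142-fold lower, or 77.7-fold without HBE replicate 3. CDKN2B-AS1-203, the 1 transcript of the 9p21 list, had 165 counts over the HBE samples and none in A549. It overlaps exons of the protein-coding gene CDKN2A on the opposite strand.

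In the p53 list NEAT1-201 and PVT1-213 were higher and PVT1-209 lower in A549. With the replicate number as a block 1 of these 3 calls was left. PVT1-209 also lost its call without HBE replicate 1, with limma-voom and with the scalings that ended the call of SNHG15-202, and PVT1-213 lost its call without HBE replicate 2. Both NRF2 transcripts, LUCAT1-210 and LUCAT1-237, belong to LUCAT1 and were higher in A549, from few counts. LUCAT1-210 had no count in HBE and 21, 8 and 15 in A549. LUCAT1-237 had 0, 4 and 0 counts in HBE and 53, 4 and 56 in A549, so the lines overlapped. Among mesenchymal and fibroblast markers MIR100HG-227 and MIR100HG-231 were higher and ZEB1-AS1-208 lower in A549. Exons of ZEB1 lie opposite ZEB1-AS1-208. Among neural markers OLMALINC-201 was higher, at 3.50 ± 0.303 against 0.540 ± 0.160 CPM (SD, n = 3 each), and MIAT-218 lower in A549. ZEB1-AS1-208 and MIAT-218 lost their calls with the scalings that ended the call of SNHG15-202. The PPARGC1A axis, the blood and endothelial markers and the proliferation list had 0 transcripts in the table.

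**Figure D3:**
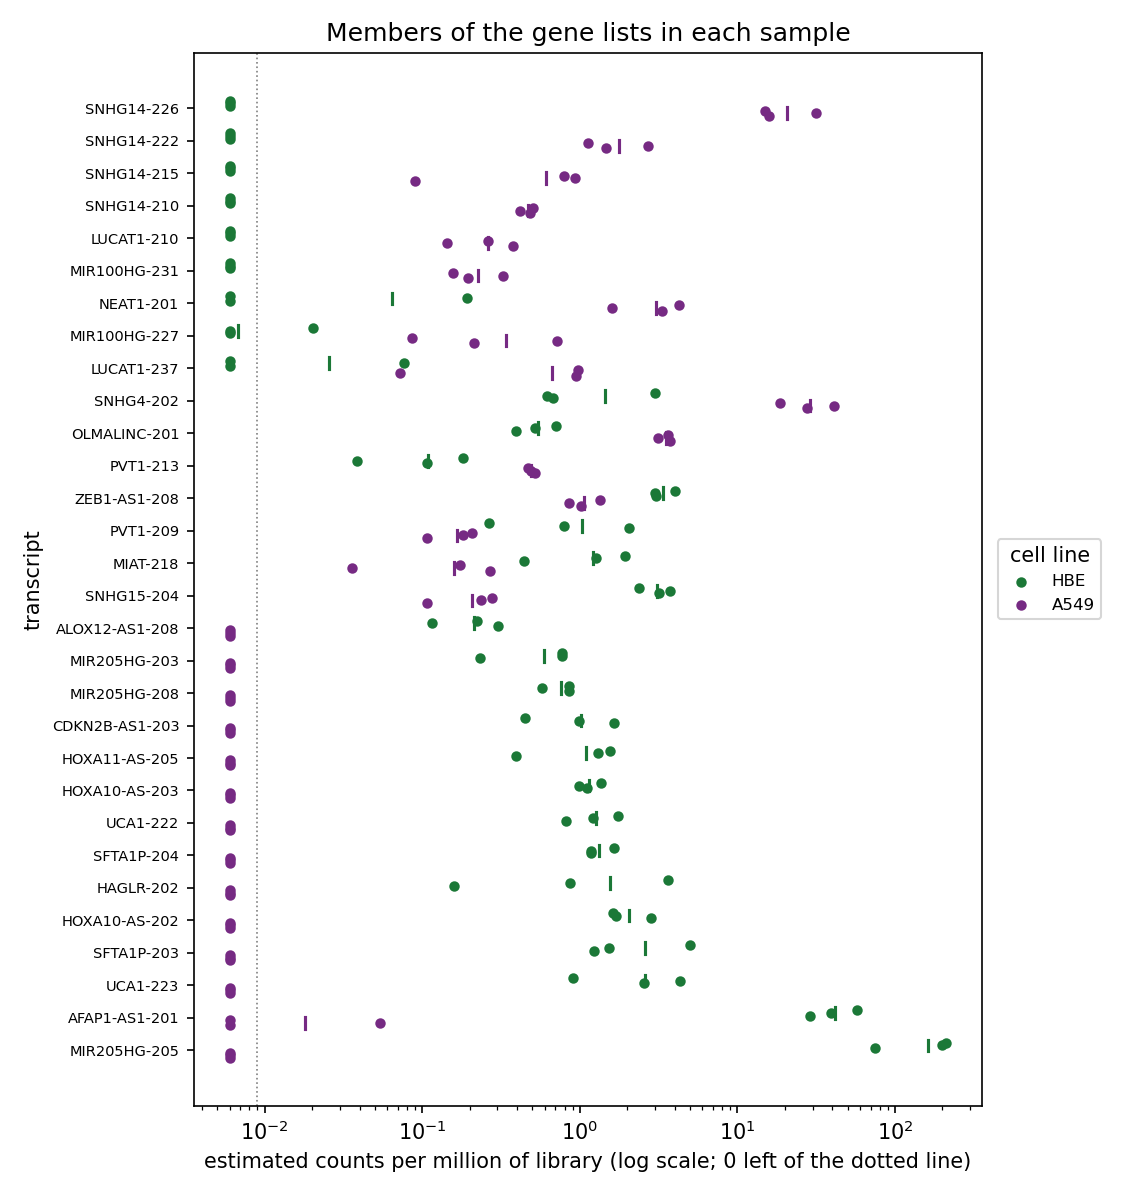
Estimated counts scaled by library size (CPM) on a log axis (x axis) for the named members of the gene lists (y axis); each point is 1 sample, short vertical lines are the means of the 3 samples of a line, and points left of the dotted line had no count. MIR205HG-205 averaged 162 CPM in HBE and SNHG14-226 averaged 20.8 CPM in A549, each with no count in the other line.

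The direction of change differed by chromosome. On chromosome 7, which carries the HOXA cluster and SNHG15, 3 annotated transcripts were higher and 29 lower in A549 (adjusted p = 0.000346 by Fisher's exact test, two-sided). On chromosome 1, which carries MIR205HG, 12 were higher and 53 lower (adjusted p = 0.000247 by the same exact test). None of the other 21 chromosomes passed. Chromosome 15, which carries SNHG14, had 24 higher and 13 lower (adjusted p = 0.0748 by the exact test). It passed when all annotated transcripts were split by sign regardless of the threshold, at 25 higher and 13 lower (adjusted p = 0.0489 by the exact test). With 1 transcript per gene, chosen after seeing the data, it passed as well, at 19 higher and 9 lower (adjusted p = 0.0424 by the exact test). Chromosomes 1 and 7 passed there too (adjusted p = 0.000549 and 0.00643 by the exact test). The exact test treats transcripts as independent, although transcripts of a gene and neighbouring genes often shared a direction. Transcripts with antisense names were higher in A549 in 40 of 114 cases and those with host names in 19 of 31, and no naming class passed (smallest adjusted p = 0.124 by the exact test over 4 classes). By GENCODE gene type, a split tested after seeing the data, 84 antisense transcripts were higher and 170 lower in A549, against 213 higher and 216 lower among the others (adjusted p = 0.000162 by the exact test over 7 types). With 1 transcript per gene 77 were higher and 156 lower (adjusted p = 0.00343 by the exact test). The lincRNA type passed too, at 142 higher and 147 lower against 155 and 239 among the others (adjusted p = 0.0434 by the exact test). Its adjusted p with 1 transcript per gene was 0.0419 by the exact test. The others in that comparison include the antisense transcripts. Antisense transcripts with exons of a protein-coding gene on the opposite strand were higher in 43 of 160 cases and those without in 41 of 94. Against the other types the adjusted p was 1.25e-06 and 0.307 by the exact test. Antisense transcripts with and without such exons were not tested against each other. Reads of the coding genes may contribute, since it is not known whether counting used the strand.

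**Figure D4:**
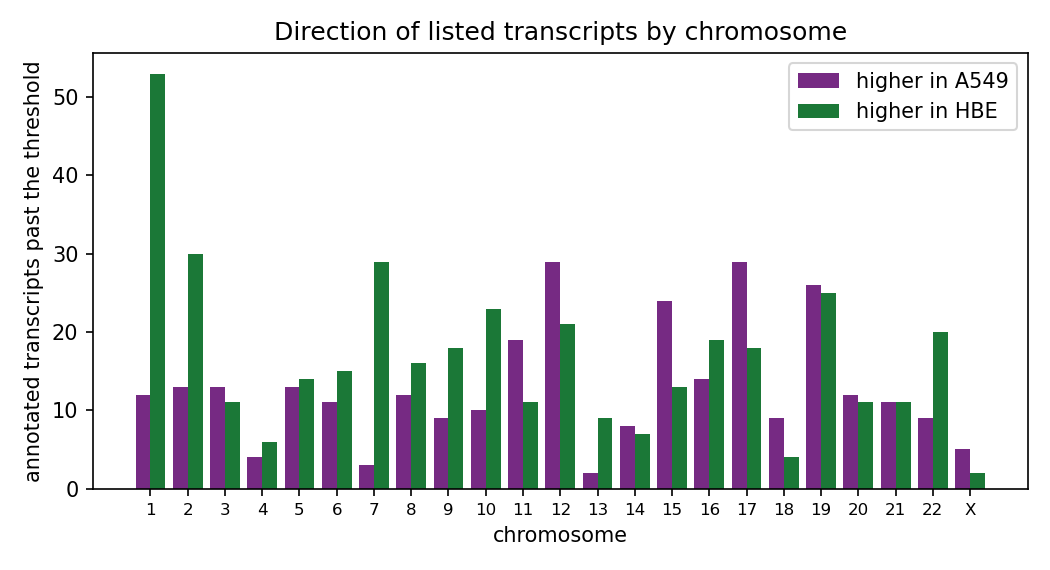
Number of annotated transcripts past the threshold (y axis, from 0) on each chromosome (x axis), split into those higher in A549 and those higher in HBE. Chromosomes 1 and 7 had 53 and 29 transcripts higher in HBE against 12 and 3 higher in A549.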

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

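The number of transcripts past the threshold was 1435, and it was 1408 to 1431 when 1 sample was left out and 1382 at an adjusted p under 0.01. Limma-voom gave 1417 calls, upper-quartile factors 1430, the likelihood ratio test 1436 and a test against a 2-fold change 1407. Requiring at least 10 counts in at least 3 samples left 941 calls and a mean of at least 50 counts left 269, because 943 and 270 transcripts were then tested. The share higher in A549, 47.7%, was then 41.45% and 40.52%. Scalings taken from the table shifted log2 fold changes by a median of 0.858 with DESeq2 size factors in edgeR and 0.86 with TMM. The median shift was 1.103 with column totals and 1.4 with the DESeq2 Wald test. The size factors were the same in edgeR and in the Wald test, so 0.858 and 1.4 differ by the method of fitting and not by the scaling. With upper-quartile factors the shift was 0.26 and 47.9% stayed higher in A549. The share was 52.65% with DESeq2 size factors in edgeR, 52.41% with the DESeq2 Wald test, 55.24% with column totals and 52.49% with TMM over the table, which was chosen after seeing the data. These gave 1301, 1307, 1240 and 1305 calls. DESeq2 with the recovered library sizes, also chosen later, gave 1435 calls, 47.74% of them higher in A549. A composition factor from the authors' fold changes, chosen later too, gave 1436 calls, 47.7% of them higher in A549. The authors' log2 fold changes exceeded the recomputed ones by a median of 0.14 over 153 transcripts.

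No effect shared by same-numbered samples was seen, since their deviations correlated at 0.02, 0.02 and -0.07. Those of differently numbered samples correlated at -0.074 to 0.065. These values cannot show that the samples were not handled in numbered pairs. With the replicate block, 1342 transcripts passed, and 1 of the 3 p53-linked transcripts.

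A mean of at least 50 counts left 8 transcripts in the lung cancer list, 6 in the platinum list, 2 each among HOX transcripts and microRNA hosts, and 1 each in the imprinted, p53-linked, airway, alveolar and club, mesenchymal and neural lists. It left 0 in the NRF2 and 9p21 lists, because fewer were tested. At least 10 counts in 3 samples left 8 microRNA hosts, 0 NRF2 and 1 mesenchymal transcript. In the neural list 1 call was left with DESeq2 size factors, the DESeq2 Wald test, column totals and TMM over the table, as MIAT-218 missed the threshold.

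Of 999 values of the 57 other transcripts that the rule named, 977 kept direction and call under the alternatives. Another 22 kept direction and lost the call, and 0 reversed. The losses were in 6 transcripts. GLIDR-202 kept its call in every fit that tested it, with log2 fold changes of 3.28 to 4.62 when 1 sample was left out, and so did GLIDR-201. Against annotated transcripts alone, chosen after seeing the data, the adjusted p was 0.0314 for the HOX, snoRNA host and imprinted lists by Fisher's exact test. Most transcripts had few counts: the median transcript had a mean of 13.8 counts.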

Other observations

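The tests on opposite transcripts of a locus and on splits of the samples, and the transcripts named below, were chosen only after the result was seen. The copies of GLIDR and a run of genes around SNHG14 had also been seen before the tests on windows and neighbours were set up. The patterns rest on transcripts that the authors had selected.

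Some neighbouring genes outside the lists formed runs with a single direction. On chromosome 1, 6 genes adjacent among the annotated genes of the table, from FAM87B to AL691432.2 (817371 to 1615795) were all higher in HBE. On chromosome 16, 5 genes from AC116552.1 to AC135782.1 (88512960 to 89052965) were higher in HBE, and on chromosome 17, 4 genes from AC007952.6 to AC106017.2 (19141017 to 19220473) were higher in A549.

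As a hypothesis, neighbouring genes may share a direction because regions differ between the lines. Of 150 adjacent gene pairs within 500 kb, 73.33% had a single direction, against 55.2% on average when directions were shuffled within chromosomes (permutation p = 0.0001, the smallest that 10000 shuffles can give). A single transcription unit or copies annotated as several genes could give the same picture. Among 16 pairs on opposite strands, at least 5 kb apart and free of copies, 56.25% had a single direction, against 52.28% for shuffled directions (permutation p = 0.47). That explanation stays open, since 16 pairs are too few to decide.

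GLIDR reads may in part come from near-identical copies. Of the 100-nt windows of its 2 transcripts, 63.05% occur without a mismatch in transcripts of other genes, most often AL512625.1, and of the 150-nt windows 45.7% do. The copy BX088651.4 was higher in A549 as well, so a rise of the GLIDR gene itself and a rise of its relatives both stay open.

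Transcripts of a single gene or assembled locus mostly moved together. Of 114 loci with several transcripts in the table, 9 had transcripts in both directions, against 66.1 on average for shuffled directions (permutation p = 0.0001, the smallest that 10000 shuffles can give). LRRC75A-AS1, PVT1, ZFAS1, CTBP1-DT and MSTRG.31835 were among them. Estimates from few counts could produce such pairs, and 22.22% of the 9 loci, LRRC75A-AS1 and MSTRG.31835, had a mean of at least 50 counts in both directions. This share does not decide between few counts and a difference in isoform use.

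Of the 10 splits of the 6 samples into groups of 3, 1 gave as many differing transcripts as the real split, which is the real split itself, with 1435 transcripts against 0 in the highest of the others. With 10 splits the share is at least 1 in 10, so it cannot fall below 0.05. The transcripts had also been selected on the real split.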
